A study of Macaca mulatta with 36 samples.

How the data were processed

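The data set held 36 arrays of RNA from peripheral blood mononuclear cells (PBMC) of 12 rhesus macaques infected with SIVmac251, a simian immunodeficiency virus. Each animal was sampled before infection (baseline) and at weeks 3 and 7 after infection. Per the labels, 4 animals had rapid progression (3149, 3176, 3201 and 3206), 4 typical progression (3137, 3142, 3204 and 3226) and 4 slow progression (3133, 3213, 3214 and 3220).

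The deposited table gave 1 linear intensity per probe set and array, for 7129 probe sets, 58 of them controls. The software that made these intensities is not given in the sources used here. The deposited intensities had already been brought to a shared scale: the mean after trimming 2% of the probe sets from each end lay between 2480 and 2508 on every array. Between 26.2% and 38.8% of the values on an array were below 0. The probe sets were designed on human sequences, so macaque RNA was measured across species, and a low value can stem from sequence differences as well as from low expression. Gene symbols came from the platform annotation: 5709 probe sets had 1 symbol, 321 had several, and 1099 were not listed there and stay unnamed. Probe sets with several symbols were not named. Of each gene, the probe set brightest over all arrays stood for it in the gene lists (4315 genes). A further probe set that did not follow is given for ITGB3, HLA-DQB1, LCK, NR4A3, CXCL8 and PAK2 but not for every named gene.

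From these intensities, values below a floor of 251 units (0.1 of the shared trimmed mean) were set to the floor, and log2 was taken. Between 21.6% and 31.5% of the tested values on an array were at the floor, so folds of dim genes are understated, and a fold against a group wholly at the floor is a lower bound. A probe set was tested where it exceeded 501 units on at least 4 of 36 arrays. This kept 5919 probe sets and left out 1152 as dim; of those kept, 4807 had 1 gene symbol, 270 several and 842 none. No array pair of the 630 held identical values, and the highest Spearman correlation of a pair was 0.926. The number of arrays limits the precision.

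Changes over time were tested with limma 3.58.1 in R 4.3.3, in 1 fit over all 36 arrays with each group at each time as a term and the animal as a block. Progression groups at 1 time were compared in fits of the 12 arrays of that time. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method, with adjusted p under 0.05 called. Errors of log2 changes are standard errors. Because the labels name the animal, the animal number pairs the arrays. Arrays of 1 animal deviated together with a mean r of 0.126 over 36 pairs, against -0.04 over pairs of different animals. Of these pairs, 24 had an r over 0.1, and 25 of 36 arrays were closest to an array of the same animal.

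Before the data were examined, 21 gene lists were fixed: interferon-stimulated genes, interferon-gamma-inducible and class I genes, MHC class II, cytotoxic lymphocyte, T cell, naive and helper T cell, B cell, plasma cell, monocyte, dendritic cell, granulocyte, platelet, erythroid, cell cycle, immediate-early, inflammatory and NF-kappaB, apoptosis, lentivirus receptor and restriction, heat shock, ribosomal protein and oxidative phosphorylation genes. Each was tested with camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 21 lists. Counts of list members use the adjustment over all probe sets unless "adjusted over the list alone" is written. List scores are means over members per array, and their baseline levels and changes were compared between groups by exact permutation tests, whose smallest p for 4 animals against 4 is 0.0286.

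The genes named were chosen by a rule fixed at the same time. For weeks 3 and 7 over all animals it took the 10 largest rises and 10 largest falls among called genes that moved alike in at least 10 of 12 animals. In other comparisons it took the 5 largest in each direction, or the 3 smallest p where nothing was called. Up to 4 called members of each list were added, as were MX1, GZMB, CD8A, CD4, MS4A1, CD14 and HBB; 1 further gene of the rule is not reported here. Other list members given as examples were chosen after their values were seen.

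The methods were tested on simulated data with the baseline means and residual spread of the 5919 tested probe sets, where changes were placed on 100 bright probe sets for each of 2 sizes. For week 3 over all animals, 75% of changes of 1 on the log2 scale and 95% of changes of 2 were recovered, and 8.11% of calls were false. For week 3 in 1 progression group the recoveries were 37% and 72%, for the rapid minus slow difference of change 11% and 48%, and for rapid against slow at week 3 4% and 54%. In 20 simulated lists the 1 shifted list was called and 0 others were. All simulated probe sets varied independently of each other, so false list calls from correlated members could not arise there.

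Alternatives were quantile normalization, floors of 100.2 and 501 units, no filter, a filter of 1002 units on 12 arrays, trended and robust variance moderation, each animal left out in turn, no replicate block, a random block, a linear trend over the groups and all 36 arrays in the group fits. Added after the data were seen were fits without 3 typical baseline arrays that stood apart (1 typical baseline array, that of 3204, then remains, and the spread comes from other arrays), with rapid and slow animals alone, without 2 rapid arrays of extreme spike controls, and with a floor of 1002 units. A check of technical batches was not possible because the labels gave none.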

Results

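The arrays compared blood mononuclear cells before infection with cells from the same animals 3 and 7 weeks later, and animals whose later disease course was rapid, typical or slow. A shared trimmed mean of 2506 units set the scale of all 36 arrays. On a principal component analysis the first component (19.5% of variance) separated the baseline arrays of the typical animals 3137, 3142 and 3226, at 87.3 to 120, from the other arrays, which lay between -25.3 and 4.48. In these 3 arrays the T cell list score differed by -1.42 on the log2 scale and the B cell score was higher by 0.69 than the mean of the other 9 baseline arrays. Shifts were not limited to these lists. The cell cycle score differed by -0.55, the cytotoxic by -0.47, the heat shock by -0.39 and the class II by -0.34. Interferon-stimulated and inflammatory scores differed by 0.50 and 0.44. Changes from baseline in these 3 animals are taken from these values.

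**Figure D1:**
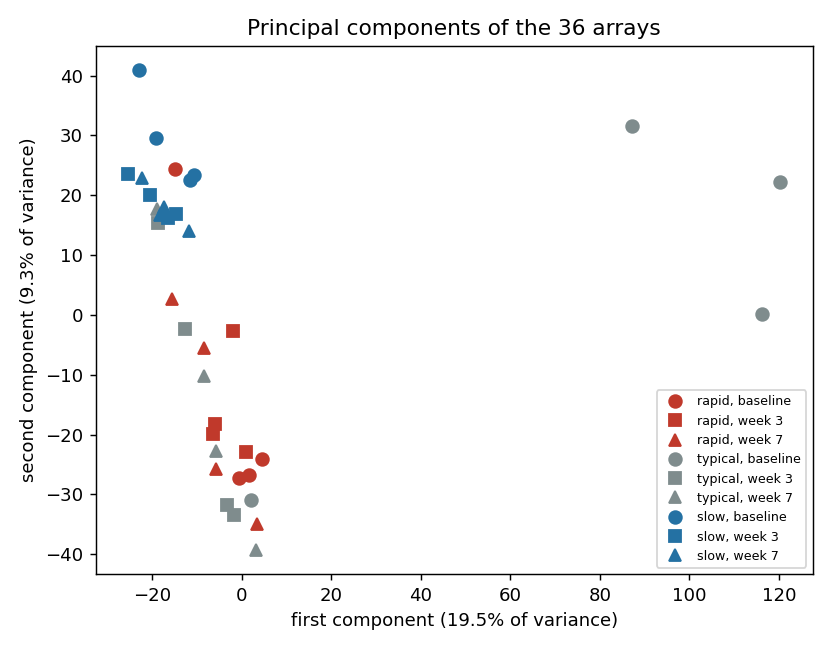
Principal components of the 36 arrays, with the first component (19.5% of variance) on the horizontal axis and the second (9.26%) on the vertical axis. Each symbol is 1 array, coloured by progression group and shaped by time; 3 typical baseline arrays lie at 87.3 to 120 on the first component.

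The first question was which genes changed by week 3 of infection. IFI27, an interferon-stimulated gene, was at the floor on 12 of 12 baseline arrays and above it on all later arrays, a rise of at least 118-fold (6.88 ± 0.27 on the log2 scale, n = 12, adjusted p = 1.54e-13). Of the called falls, 3 of the largest were seen in 12 of 12 animals: SMAD7, an inhibitor of TGF-beta signalling (fell by 3.81 ± 0.46), the nuclear receptor gene NR4A3 (fell by 3.40 ± 0.41) and IL1B, which encodes the cytokine interleukin 1 beta (fell by 3.32 ± 0.41). F13A1, which encodes a coagulation factor subunit carried by platelets and monocytes, rose 5.56-fold in 12 of 12 animals. CX3CR1, a chemokine receptor of cytotoxic lymphocytes and monocytes, rose 3.76-fold, also in 12 of 12. Other large rises were those of ITGB3, STIP1, CTTN, HELZ, NKG7, SERINC3 and N4BP2L2-IT2, from 1.87 to 2.93. The ITGB3 probe set, at 2.93, was at the floor on 10 of 12 baseline arrays, so the size of its change is not well measured. For ITGB3 a brighter probe set did not pass (log2 change -0.07, adjusted p = 0.908), nor did a further NR4A3 probe set (-0.42, adjusted p = 0.648). Other large falls were those of PLK3, RGS2, EGR3, NR4A2, PTGS2, CGA and ERH, with log2 changes from -3.05 to -2.46.

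Of 5919 probe sets, 559 changed at week 3, 278 higher and 281 lower; 1393 had an unadjusted p under 0.05, where 296 were expected by chance. Without the replicate block 353 were called, so pairing by animal moved the count. Without the 3 typical baseline arrays that stood apart, a fit with 1 typical baseline array left, 119 were called, 101 of them shared with the 559, and with rapid and slow animals alone 126 were called, 112 of them shared. Leaving out 1 animal gave 296 (without 3220) to 944 (without 3204), and removing any of 10 animals moved the count by over 1.5 times. IFI27, SMAD7, NR4A3, IL1B, PLK3, RGS2, EGR3, NR4A2, PTGS2, F13A1, CX3CR1 and ITGB3 passed in both smaller fits, while STIP1 did not (adjusted p = 0.118 and 0.13). SERINC3 and CGA did not pass in either fit (adjusted p = 0.0876 and 0.402 for SERINC3, 0.317 and 0.142 for CGA), nor did NKG7 and N4BP2L2-IT2 (0.215 and 0.377, 0.109 and 0.153). With rapid and slow animals alone CTTN, HELZ and ERH did not pass (0.0594, 0.0914 and 0.102).

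Gene lists of antiviral and cytotoxic function shifted upward at week 3. Of 30 measured interferon-stimulated genes, 5 rose, 0 fell and 25 did not pass (7 rose when adjusted over the list alone). Examples were IFI27, IFI44 (1.07 ± 0.18), the restriction factors MX2 (1.43 ± 0.33) and BST2 (0.89 ± 0.17), both of which the lentivirus list also holds. The list was called upward (camera adjusted p = 8.62e-05), a call lost at adjusted p = 0.185 with an estimated correlation. MX1 (1.24 ± 0.42, adjusted p = 0.0675) and ISG15 (1.24 ± 0.42, adjusted p = 0.0646) did not pass at week 3. Of 18 interferon-gamma-inducible and class I antigen processing genes, 5 rose and 13 did not pass (8 rose adjusted over the list alone), among them the guanylate-binding protein genes GBP2 (1.63 ± 0.28) and GBP1 (1.56 ± 0.37) and the immunoproteasome subunit PSMB8 (1.32 ± 0.32); the list was called upward (adjusted p = 0.00017, and adjusted p = 0.0338 with an estimated correlation). Without the 3 arrays MX2, BST2, GBP1 and PSMB8 did not pass (adjusted p = 0.127, 0.142, 0.389 and 0.0876).

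Of 15 cytotoxic lymphocyte genes, 7 rose and 8 did not pass (8 rose adjusted over the list alone). The protease genes GZMA (1.55 ± 0.23, 12 of 12 animals) and GZMH (1.52 ± 0.29), the chemokine gene CCL5 (1.64 ± 0.32) and the NK receptor gene KLRD1 (1.36 ± 0.33) were examples, and IFNG rose by 1.19 ± 0.27. GZMB (0.55 ± 0.22, adjusted p = 0.123) and CD8A (0.47 ± 0.54, adjusted p = 0.65) did not pass. The list was called upward (adjusted p = 6.86e-06, and adjusted p = 0.0377 with an estimated correlation). Without the replicate block NKG7 and KLRD1 did not pass (adjusted p = 0.0528 and 0.0679). Without the 3 arrays CCL5 and KLRD1 did not (0.0943 and 0.0803).

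Falls were called in MHC class II and inflammatory genes. Of 12 MHC class II genes, 7 fell, 0 rose and 5 did not pass (8 fell adjusted over the list alone). HLA-DMB fell by 0.85 ± 0.13 and HLA-DQB1 by 0.79 ± 0.13, each in 12 of 12 animals, and HLA-DMA and HLA-DQA1 changed by -0.62 ± 0.16 and -0.60 ± 0.16. A dim second probe set of HLA-DQB1, with no change (0.04), did not follow. The class II list was called downward (adjusted p = 8.62e-05), a call lost at adjusted p = 0.0895 with an estimated correlation. Without the 3 arrays HLA-DMA and HLA-DQA1 did not pass (adjusted p = 0.0736 and 0.346), nor did HLA-DQA1 without the replicate block (0.0502). Of 18 inflammatory cytokine and NF-kappaB genes, 3 fell and 15 did not pass (4 fell adjusted over the list alone): IL1B, PTGS2, which makes prostaglandins (-2.62 ± 0.26), and the chemokine gene CXCL8 (-1.79 ± 0.38). That list was called downward (adjusted p = 0.00594, and adjusted p = 0.0338 with an estimated correlation). CXCL8 did not pass without the 3 arrays (adjusted p = 0.215), and a further CXCL8 probe set did not pass (-0.51, adjusted p = 0.493). CD83, a maturation marker of dendritic cells, was the 1 of 7 dendritic cell genes that fell (-1.90 ± 0.20; 1 fell adjusted over the list alone), and this list was called downward (adjusted p = 0.0222, lost at adjusted p = 0.0544 with an estimated correlation).

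Markers of another cell type, the platelet, moved with infection. Of 11 platelet genes, 6 rose and 5 did not pass (6 rose and 1 fell adjusted over the list alone), among them F13A1, PPBP (1.52 ± 0.21), PF4 (1.36 ± 0.26) and CLU (1.47 ± 0.20). The list was called upward (adjusted p = 8.62e-05, and adjusted p = 0.0377 with an estimated correlation). Of 11 T cell genes, 2 rose (LCK, a T cell receptor kinase, by 1.20 ± 0.19, and CD247 by 1.26 ± 0.31; 2 adjusted over the list alone), and the list was called upward (adjusted p = 0.0289), a call lost at adjusted p = 0.185 with an estimated correlation and at 0.264 without the 3 arrays. It was also lost with the mean of all probe sets of a gene (0.0967) and without animal 3137 (0.0635) or 3149 (0.0859). A dimmer LCK probe set did not pass (-0.73, adjusted p = 0.121), and CD247 did not pass without the 3 arrays (0.542).

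Of 17 immediate-early genes, 4 rose, 3 fell and 10 did not pass (4 rose and 5 fell adjusted over the list alone), and the list was not called (adjusted p = 0.974). FOS (1.54 ± 0.15) and DUSP1 (1.01 ± 0.16) rose in 12 of 12 animals while EGR3 (-2.92 ± 0.37) and NR4A2 (-2.83 ± 0.33) fell in 12 of 12. Of 15 apoptosis genes the survival gene MCL1 rose by 1.87 ± 0.28 and BCL2A1, an NF-kappaB target, changed by -1.69 ± 0.19 (1 rose and 1 fell adjusted over the list alone; list adjusted p = 0.953). Of 8 lentivirus receptor and restriction genes, SERINC3, MX2 and BST2 rose and CXCR4, a chemokine receptor, fell by 1.07 ± 0.15 in 12 of 12 animals (3 rose and 2 fell adjusted over the list alone; list adjusted p = 0.415). The B cell marker MS4A1 changed by -1.20 ± 0.33 in 11 of 12 animals (adjusted p = 0.0272), and not without the replicate block (0.0604) or without the 3 arrays (0.584). Among the 12 B cell genes PAX5, at the floor on 8 of 12 baseline arrays, fell and CD24 rose, and neither passed without the 3 arrays (0.869 and 0.18). CCR7, a homing receptor of naive T cells, changed by -1.97 ± 0.45 (adjusted p = 0.0105; 0.119 without the 3 arrays). The remaining lists were not called: naive and helper T cell (0 rose, 1 fell; adjusted p = 0.415), B cell (1 rose, 2 fell; 0.394), plasma cell (0 and 1; 0.953), monocyte (1 and 0; 0.953), granulocyte (0 and 0; 0.974), erythroid (0 and 0; 0.974), cell cycle (4 and 0; 0.0887), heat shock (1 and 0; 0.415), ribosomal protein (0 and 1; 0.415) and oxidative phosphorylation (3 and 0; 0.0638). In these lists the numbers that rose and fell differed when adjusted over the list alone for plasma cell (0 and 2), cell cycle (4 and 1), heat shock (2 and 1) and ribosomal protein genes (0 and 0). Some were called under alternatives. The oxidative phosphorylation list was called with quantile normalization (camera adjusted p = 0.0121) and without the 2 rapid arrays of extreme spike controls (0.0457). It was called in 5 of 12 fits without 1 animal, and the cell cycle list in 3 of 12. For apoptosis genes the median change was -0.10 and the mean 0.04, and for granulocyte genes -0.08 and 0.00. CD4 (-0.34 ± 0.28, adjusted p = 0.51), CD14 (-1.06 ± 0.58, adjusted p = 0.278) and HBB (-0.52 ± 0.36, adjusted p = 0.41) did not pass.

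**Figure D2:**
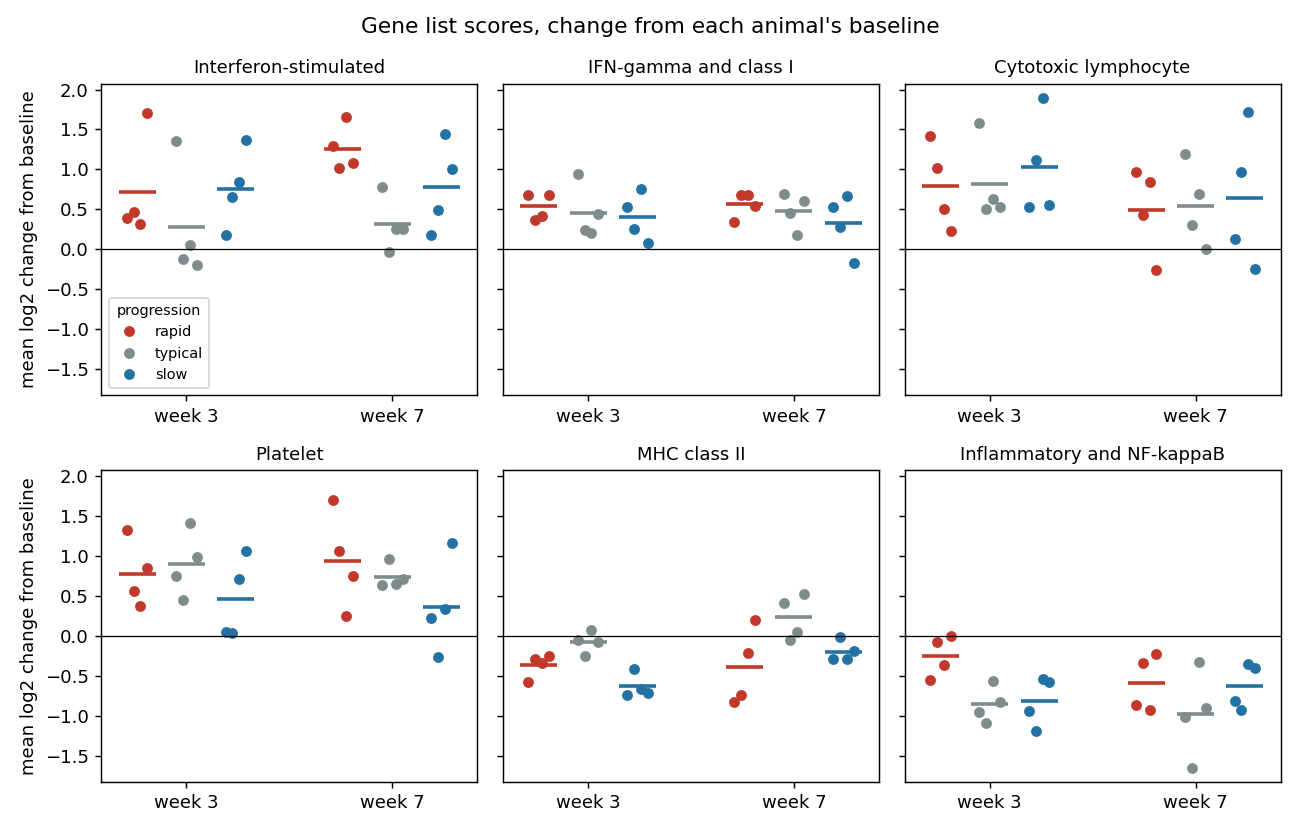
Mean log2 change of 6 gene lists from each animal's own baseline, at weeks 3 and 7. Each point is 1 animal, coloured by progression group, and each bar is the mean of the 4 animals of a group; the cytotoxic score rose in 12 of 12 animals at week 3 and the inflammatory score was below 0 in 12 of 12 at week 7.

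At week 7 IFI27 was at least 135-fold above its baseline floor (7.08 ± 0.27). MX1 rose 4.70-fold, MX2 4.64-fold and ISG15 4.33-fold, each in 11 or 12 of 12 animals. SMAD7, NR4A3, RGS2, IL1B and PLK3 fell, with log2 changes of -3.78 to -3.21, and CXCR4 had fallen by 1.99 ± 0.15 in 12 of 12 animals. NRGN rose 11.7-fold and the platelet chemokine variant PF4V1 4.54-fold. UOX, STIP1, ITGB3, CTTN and MAT2A rose by 2.17 to 2.63 on the log2 scale. The brighter ITGB3 probe set did not pass in limma at week 7 either (log2 change 0.31, adjusted p = 0.509). CGA, NR4A2, NRIP1, P2RY10 and PTGS2 changed by -2.80 to -2.38.

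At week 7, 496 probe sets were called, 256 higher and 240 lower (1407 at an unadjusted p under 0.05). Quantile normalization gave 333 higher and 195 lower. Without the 3 typical baseline arrays 168 were called, 139 of them shared, with rapid and slow animals alone 177 (148 shared), and leaving out 1 animal gave 307 (without 3220) to 899 (without 3204). Without the 3 arrays STIP1, ITGB3, MX1, CTTN, CGA, P2RY10 and ISG15 did not pass (adjusted p = 0.0559, 0.061, 0.0915, 0.0555, 0.177, 0.0665 and 0.177), and with rapid and slow animals alone NRGN and CTTN did not (0.0988 and 0.0555).

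Of 30 interferon-stimulated genes, 9 rose and 21 did not pass (12 rose and 2 fell adjusted over the list alone), and the list was called upward (adjusted p = 9.98e-07), a call lost at adjusted p = 0.133 with an estimated correlation. Interferon-gamma-inducible genes (5 of 18 rose, 8 adjusted over the list alone) were called upward (adjusted p = 0.00131; lost at adjusted p = 0.0691 with an estimated correlation), as were cytotoxic genes (5 of 15 rose, 7 over the list alone; adjusted p = 0.00127, lost at adjusted p = 0.192 with an estimated correlation). Platelet genes (4 of 11 rose, 5 over the list alone; adjusted p = 0.000231, lost at adjusted p = 0.0691 with an estimated correlation) were called upward too. PPBP was up by 1.74 ± 0.21 and PF4 by 1.72 ± 0.26, both in 12 of 12 animals. Of 18 inflammatory genes 5 fell (6 adjusted over the list alone), IL1B, PTGS2, CXCL8, NFKB1 and IL6, and this list was called downward (adjusted p = 0.00103, and adjusted p = 0.0165 with an estimated correlation). NFKB1 (-1.43 ± 0.38) did not pass without the 3 arrays (adjusted p = 0.131), and of the heat shock genes named next, 0 of 3 did (0.293, 0.226 and 0.0665). Heat shock genes were called upward (3 of 12 rose, DNAJB1, DNAJA1 and HSPE1; 6 rose and 2 fell over the list alone; adjusted p = 0.0474, lost at adjusted p = 0.446 with an estimated correlation). This heat shock call held in 5 of 12 fits without 1 animal (highest adjusted p 0.159, without 3201). It was lost with the mean of all probe sets of a gene (0.0654) and without the 2 rapid arrays of extreme spike controls (0.0651). Ribosomal protein genes were called downward (2 of 45 fell, 0 over the list alone; adjusted p = 0.000223, lost at adjusted p = 0.55 with an estimated correlation), with a median log2 change of -0.20. Only 2 of 12 class II genes, HLA-DMB (-0.69 ± 0.13) and HLA-DQB1 (-0.45 ± 0.13; 0.0729 without the replicate block and 0.282 without the 3 arrays), fell at week 7 (3 over the list alone), and that list was not called (adjusted p = 0.0861). Other lists were not called at week 7. GZMB (0.19 ± 0.22, adjusted p = 0.628) and MS4A1 (0.13 ± 0.33, adjusted p = 0.853) did not pass.

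**Figure D3:**
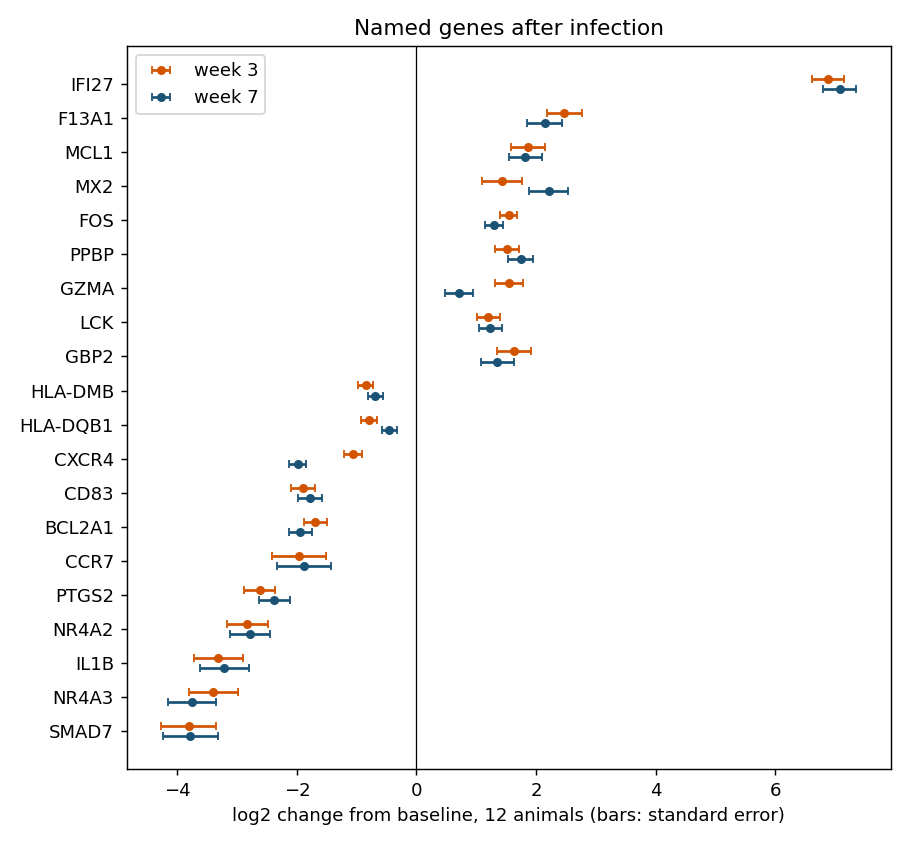
Log2 change from baseline of 20 named genes over 12 animals, at week 3 and week 7, with bars showing the standard error. IFI27 lies at 6.88 and 7.08, a lower bound because its baseline was at the floor, and SMAD7 at -3.81 and -3.78.

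Between weeks 3 and 7 the chemokine receptor CXCR4 was the 1 called probe set, 1.90-fold lower at week 7 (log2 change -0.93 ± 0.15, adjusted p = 0.0212); 322 had an unadjusted p under 0.05. Leaving out 1 animal gave 0 to 2 called probe sets, and 26 of 100 splits of the samples, the real one included, gave as many calls. Without the 3 typical baseline arrays, with rapid and slow animals alone or without 2 rapid arrays of extreme spike controls, 0 were called (adjusted p for CXCR4 = 0.056 without the 3 arrays). In camera, interferon-stimulated (adjusted p = 0.0152), class II (4.49e-05), B cell (0.0285), dendritic cell (0.0152) and heat shock genes (0.032) were called higher at week 7 and cytotoxic (0.0152) and ribosomal protein genes (2.9e-07) lower. With an estimated correlation 0 of these lists were called (adjusted p = 0.52, 0.216, 0.344, 0.162, 0.419, 0.419 and 0.482 in this order). In limma 0 single members of these lists were called, and adjusted over the list alone 1 cytotoxic gene fell and 1 B cell and 2 dendritic cell genes rose. Leaving out animal 3201 or 3226 left 3 lists called, and leaving out 3176 left 4. The interferon-stimulated call held in 8 of 12 fits without 1 animal, the cytotoxic call in 9, the dendritic cell call in 10, the B cell call in 5 and the heat shock call in 6, and the last was lost with the mean of all probe sets of a gene (adjusted p = 0.0534).

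Within the rapid progression group, IFI27 rose by at least 122-fold at week 3 and 306-fold at week 7. IL1B (-3.95 ± 0.71), PLK3 (-4.34 ± 0.80), SMAD7 (-3.85 ± 0.79), NR4A2 (-3.77 ± 0.58) and NR4A3 (-3.53 ± 0.71) fell at week 3, and NR4A3, PLK3, RGS2, SMAD7 and P2RY10 fell at week 7. F13A1 rose 6.05-fold at week 3, and MX1 (3.33 ± 0.73) and MX2 (3.03 ± 0.57) rose at week 7. At week 3 F2RL2, H2AC6 and RPS6KA1 also passed, and at week 7 NRGN and UOX. In limma, 59 probe sets were called at week 3 (24 higher, 35 lower) and 64 at week 7 (30 higher, 34 lower). Without the replicate block 30 were called at week 3, where PLK3, RPS6KA1 and F2RL2 did not pass (adjusted p = 0.0569, 0.0548 and 0.162), and at week 7 MX1, NRGN and P2RY10 did not (0.142, 0.176 and 0.108). Leaving out 1 animal gave 2 (without 3201) to 60 at week 3 and 15 (without 3149) to 76 at week 7, and without the 2 arrays of extreme spike controls 23 and 38 were called.

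In the slow progression group IFI27 rose by at least 129-fold at week 3 and 79.5-fold at week 7. At week 3 IFNG (2.24 ± 0.48), GBP2 (2.22 ± 0.49), GZMA (1.93 ± 0.40) and CENPX rose, and SMAD7, PTGS2, NR4A3, IER3 and CXCL8 fell (log2 changes -4.22 to -3.05). At week 7 MX2 (2.57 ± 0.57), KLF6, FOS and CENPX rose, and SMAD7, PLK3, IER3, NR4A3 and the growth arrest gene GADD45A (-3.11 ± 0.50) fell. The counts were 28 (8 higher, 20 lower) and 42 (8 higher, 34 lower). Without the replicate block they were 15 and 22, and GBP2, CENPX and GZMA did not pass at week 3 (adjusted p = 0.072, 0.072 and 0.103), nor CENPX, KLF6 and PLK3 at week 7 (0.0861, 0.0702 and 0.187). With 1 animal left out they were 5 to 30 and 12 to 43, lowest without 3220.

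In the typical group 1193 probe sets were called at week 3 (427 higher, 766 lower) and 1177 at week 7 (417 higher, 760 lower) with the 3 baseline arrays that stood apart among the 4 of the group. Without them 1 typical baseline array (3204) remains, other groups supply the spread, and the loss of calls is in part set by the design; 3 and 2 were called, IFI27 among them (log2 changes 6.56 and 6.52). Quantile normalization turned the split to 548 higher and 493 lower at week 3 and to 550 higher and 463 lower at week 7. The largest changes, in NRGN, CYC1, LMF2, AP2M1, MYH10, NOS1, CALB1, CGA and PRB2 at week 3 and UBA1, THAP11, CRHR1, BRS3 and P2RX1 at week 7, did not pass in that fit. With 1 animal left out the counts were 552 (without 3226) to 1729 (without 3204) and 491 (without 3142) to 1628 (without 3204).

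Whether the change after infection differed with progression was tested directly. The 3 groups differed in change for 262 probe sets at week 3 and 210 at week 7, led by KCNJ10 and PAK2 at both weeks, then CCL17, PRL and KIFC1 at week 3 and EPO at week 7; without the 3 typical baseline arrays, with 1 typical baseline array left, 2 and 2 did, and leaving out 1 animal gave 10 (without 3226) to 912 (without 3204) and 4 to 814. The rapid minus slow difference was called for 2 probe sets at week 3, TOP1 (2.77 ± 0.47, adjusted p = 0.0249) and an unnamed one, and for 1 unnamed one at week 7; without the replicate block 1 was called at week 3 and TOP1 did not pass (adjusted p = 1). At an unadjusted p under 0.05 these differences counted 254 probe sets at week 3 and 259 at week 7, where 296 were expected by chance. This TOP1 probe set was at the floor on 2, 5 and 7 of 12 arrays at baseline, week 3 and week 7. A PAK2 probe set was at the floor on 7, 10 and 12 of 12 arrays at these times, so its change at week 7 rests on baseline values alone. A further PAK2 probe set, at the floor on 0 arrays, did not pass in limma over all animals. Its log2 change was -0.41 at week 3 (adjusted p = 0.0927) and -0.12 at week 7 (adjusted p = 0.668). At week 7 the rapid minus slow difference of change was called higher than in the other genes for the lists of interferon-stimulated, monocyte and lentivirus genes (camera, medians 0.48, 0.38 and 0.85; adjusted p = 0.0246 each), and these calls were lost at adjusted p = 0.55, 0.464 and 0.209 with an estimated correlation. Leaving out animal 3133 or 3213 left 0 of them called in camera, and leaving out 3206 left 1. Without 3201 the interferon-stimulated and monocyte calls were lost, and without 3149 the interferon-stimulated call was lost. In fits without 1 animal the interferon-stimulated and monocyte calls each held in 8 of 12, and the lentivirus call in 9. The monocyte call was also lost with quantile normalization (0.0818) and without the replicate block (0.0821). By list score, which compares the groups directly, the interferon-stimulated genes changed by 1.26 ± 0.29 (SD, n = 4) in rapid and 0.78 ± 0.56 (SD, n = 4) in slow animals (exact permutation p = 0.2, adjusted p = 0.771). The monocyte genes changed by 0.10 ± 0.47 (SD, n = 4) in rapid and -0.37 ± 0.32 (SD, n = 4) in slow animals (exact permutation p = 0.143, adjusted p = 0.75). The lentivirus genes changed by 0.69 ± 0.28 (SD, n = 4) in rapid and -0.11 ± 0.16 (SD, n = 4) in slow animals (exact permutation p = 0.0286, adjusted p = 0.4). Over baseline levels and changes together, 0 of 126 score comparisons passed adjustment (14 at an unadjusted exact permutation p under 0.05). Some of the 14 were baseline levels, such as that of the interferon-stimulated genes among the 3 groups (exact permutation p = 0.00346, adjusted p = 0.0727). That level was 11.01 in typical, 10.52 in rapid and 10.45 in slow animals. In the 3 typical baseline arrays that stood apart it was 0.50 above the mean of the other baseline arrays. With 1 animal left out 5 passed without 3213, 3 without 3204 and 1 without 3142, 3149 or 3206, and 1 passed with a floor of 100.2 units. The smallest adjusted p, 0.0509, was that of the class II change at week 3 among the 3 groups. This change too is taken from the 3 typical baseline arrays that stood apart, where the class II score differed by -0.34.

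Groups were compared at each time. At baseline 414 probe sets differed among the 3 groups, led by EOLA1, KCNJ10, RASSF2 and ETV4, and 833 between typical and slow animals (642 higher and 191 lower in typical; 280 and 277 with quantile normalization); without the 3 arrays, with 1 typical array left, 8 differed among the groups. Rapid and slow animals differed in 2 probe sets at baseline, ETV4 (2.73 ± 0.35 higher in rapid, adjusted p = 0.0142; 0.0574 without the 3 arrays) and an unnamed one. At week 3, 2 differed among the 3 groups (ROM1 and SHBG), and 0 between rapid and slow in limma (539 at an unadjusted p under 0.05). ZNF37A and ELAVL1 had the smallest adjusted p there, 0.0551. The week 3 arrays of these 2 groups also differed in quality measures. Medians were 943 to 1084 units in rapid and 717 to 897 in slow animals. The ratio of the actin control signal at the transcript's end to that at its start was 1.67 to 3.12 in rapid and 1.56 to 1.64 in slow animals. At baseline and week 7 the ranges of the 2 groups overlapped. Whether array quality bears on the group comparisons was not tested. At week 7, 10 differed among the groups and 11 between rapid and slow, 5 higher in rapid (PRPH, SEMA3C, CXADR, SERPINC1 and SC5D) and 6 lower (CA7, CYP2A13, GABRB1, TLE3, SLC7A6 and an unnamed one); quantile normalization gave 2 higher and 5 lower. Leaving out 1 animal gave 0 (without 3149) to 24 (without 3137) for that last comparison, 0 (without 3204, 3214 or 3226) to 37 (without 3137) for the groups at week 7, 54 to 1444 for the groups at baseline and 1 to 28 for rapid against slow at baseline.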

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

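The tests of a swap with an array drawn after infection, of typical progression itself, of a smaller share of monocytes, of baseline bleeds handled differently and of platelet RNA by the list test were chosen after the result was seen, as was the comparison of deviations on alternate probe sets. For the B cell and bright probe set tests the bounds were written first. The platelet bounds were recorded as written after, those of the relation ahead of those of the list test. The use of quartiles or a 95% interval to read the tests was set after the values were seen.

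The baseline arrays of typical animals 3137, 3142 and 3226 lay apart from the other arrays; without them 1 typical baseline array remains, too few to test the typical group. Noise independent in each array is argued against by the mean correlation of 0.632 between their deviations (0.637 and 0.626 when the arrays were picked on alternate probe sets and compared on the others), and a swap with an array drawn after infection by IFI27, at the floor on 3 of 3. Typical progression itself cannot be told apart, since the baseline array of the remaining typical animal 3204, at 2.15 on the first component where the other 32 arrays lay between -25.3 and 4.48, is 1 array. The 3 arrays also differed in intensity, with medians of 1255, 1150.4 and 1232.3 units, against at most 1148.6 on the other 33 arrays. The array of 3142 barely passed this bound. On those of 3142 and 3226, 38.8% and 38.0% of values were below 0, against at most 34.5% on the other 33. The array of 3137 had 29.9%, inside that range. The 10th percentile was -6306 and -5506 units on the arrays of 3142 and 3226 and -2045 on that of 3137. On the other 33 arrays it was no lower than -2370. The array of 3142 also had an actin end-to-start ratio of 3.39, against at most 3.12 on the other 33 arrays. Its GAPDH ratio was 0.888, against at least 0.979. A cause shared by the 3 arrays, such as a batch in handling or hybridisation, may explain the pattern and stays open, since the labels give no batch.

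Inflammatory genes such as IL1B and PTGS2 fell at both weeks, as did NR4A2, while the immediate-early list was not called at week 3 (adjusted p = 0.974) and FOS rose; infection itself is the biological explanation the design names, untested because no animal stayed uninfected. To test a smaller share of monocytes, the called inflammatory falls were set against the monocyte list. These falls were log2 changes of -1.79 or lower at week 3 and -1.10 or lower at week 7. The monocyte list had median log2 changes of -0.13 at week 3 (quartiles -0.61 and 0.20) and -0.30 at week 7 (quartiles -0.47 and 0.04). The monocyte list as a whole thus did not fall as far as these genes. Genes called for their falls lie low by selection, however, so the comparison does not decide. The whole inflammatory list had medians of -0.29 and -0.43, and a smaller share of monocytes stays open. Platelet RNA that lowers all other genes alike is argued against as the whole cause by the fall of the inflammatory list relative to other genes (camera adjusted p = 0.0338 at week 3 and 0.0165 at week 7 with an estimated correlation). These are the list calls that raised the pattern and not a separate test. A platelet effect that is unequal over genes, or a part in the falls, stays open. The relation tested first did not decide: over 12 animals the platelet and inflammatory list changes had r = 0.360 (95% interval -0.269 to 0.774, permutation p = 0.245, adjusted p = 0.451; rho = 0.301, permutation p = 0.345, adjusted p = 0.690; 2 relations tested), and r = -0.0212 without the 2 animals farthest from the median. Baseline bleeds handled differently from both later bleeds could give the same falls and cannot be told apart from infection, because every baseline bleed came first and 1 probe set was called between week 7 and week 3. A measure of RNA quality did differ with time. The ratio of the GAPDH control signal at the transcript's end to that at its start rose from baseline to week 3 in all animals but 3206 and 3214. An example is 3149 (0.979 to 1.29), while in 3206 it went from 1.21 to 1.03. At week 7 it was above baseline in all but 3133, 3204 and 3206. Whether RNA quality bears on the falls was not tested.

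MHC class II genes fell at week 3 in 7 of 12 members. Compression of the brightest probe sets is argued against by the median log2 change of -0.0403 in 178 other bright probe sets (quartiles -0.16 and 0.10). A smaller share of B cells may contribute and cannot be told apart: over 12 animals the B cell and class II list changes had r = 0.241 (95% interval -0.386 to 0.716, permutation p = 0.451, adjusted p = 0.451; rho = 0.126, permutation p = 0.701, adjusted p = 0.701), and r = -0.0559 without 2 animals. Infection itself stays open, untested.

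An animal lay far from the other 3 of its group in 6 of 126 list scores, where chance gives about 6.3. The interferon-stimulated score at week 3 changed by 1.71 in rapid animal 3206, against 0.32 to 0.47 in the others, and by 1.36 in typical animal 3137, against -0.19 to 0.05. The week 3 array of animal 3206 is 1 of the 2 with extreme spike controls, and the scores of animal 3137 are taken from a baseline array that stood apart. The cytotoxic score at week 3 was 1.58 in typical animal 3137, against 0.51 to 0.63. The lentivirus score at week 3 was -0.55 in slow animal 3133, against 0.14 to 0.18. In slow animal 3220 the dendritic cell score at week 7 was -0.70, against -0.19 to -0.14, and the heat shock score was -0.27, against 0.30 to 0.37.

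Progression groups differed in their change for 262 probe sets at week 3 and 210 at week 7, and the rapid minus slow change was called for 2 and 1. The counts of 262 and 210 take in the 3 typical baseline arrays that stood apart. Leaving out 1 animal gave 10 (without 3226) to 912 (without 3204) at week 3 and 4 (without 3226) to 814 (without 3204) at week 7. At week 7 the rapid minus slow difference of change was called higher than in the other genes for the interferon-stimulated, monocyte and lentivirus lists, with medians of 0.48, 0.38 and 0.85 (adjusted p = 0.0246 each). These calls ended at adjusted p = 0.55, 0.464 and 0.209 with an estimated correlation, and the monocyte call also with quantile normalization (0.0818) and without the replicate block (0.0821). The mean monocyte score changed by 0.10 in rapid and -0.37 in slow animals. Leaving out animal 3133 or 3213 left 0 lists called, and leaving out 3206 left 1. Without 3201 the interferon-stimulated and monocyte calls were lost, and without 3149 the interferon-stimulated call was lost. In fits without 1 animal the interferon-stimulated and monocyte calls each held in 8 of 12, and the lentivirus call in 9.

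Other splits of the samples tested whether chance could give as many calls. Chance was excluded for week 3 in all animals (1 of 100 splits, 559 against at most 125 in the others) and week 7 in all animals (1 of 100, 496 against 133). The share of splits was also under 0.05 for the groups at baseline (1 of 100, 414 against 261, with the 3 arrays that stood apart among the typical ones). So it was for the groups at week 7 (1 of 100, 10 against 9). It was 1 of 35, the smallest share that 35 splits can give, for rapid against slow at week 7 (11 against 6). The rapid minus slow change at week 3 had the same share (1 of 35, 2 against 1). These shares were not adjusted over the comparisons, so they alone do not exclude chance. With 1 animal left out the count for the groups at week 7 was 0 (without 3204, 3214 or 3226) to 37 (without 3137), and for rapid against slow at week 7 it was 0 (without 3149) to 24 (without 3137). The count of 2 at week 3 is small: 254 probe sets had an unadjusted p under 0.05, where 296 were expected by chance, and without the replicate block TOP1 did not pass (adjusted p = 1). For the change among groups, 4 of 100 splits gave as many at week 3 (262 against 359) and 4 of 100 at week 7 (210 against 269). At each week the other 3 such splits put the 3 animals with baseline arrays apart in 1 group, and they were 3 of the 8 splits drawn with these animals together, the rest of which gave fewer calls. Chance was not excluded for week 7 against week 3 (26 of 100, 1 against 2), the rapid minus slow change at week 7 (2 of 35, 1 against 1) or rapid against slow at baseline (7 of 35, 2 against 11). It was not excluded for the groups at week 3 (18 of 100, 2 against 5) or rapid against slow at week 3 in limma (35 of 35, 0 against 5; 539 at an unadjusted p under 0.05). Within 1 group the 8 splits are too few for a share under 0.05. There the real count and highest other were 59 and 1 at week 3 and 64 and 2 at week 7 in rapid animals, 28 and 1 and then 42 and 3 in slow animals, and 1193 and 1070 and then 1177 and 882 in typical animals. The high typical splits swapped the times of animal 3204, and swapping 3137, 3142 or 3226 gave 0 calls in limma.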

How the results depend on the processing

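The tests without the 3 typical baseline arrays, with rapid and slow animals alone, without 2 rapid arrays and with a floor of 1002 units were chosen after the result was seen. Over the comparisons, 228 of 455 alternative counts lay within 1.5 times the value reported. Of the named gene values under alternatives, 6299 kept their direction and side of the threshold, 1706 lost the call, 51 gained one and 17 changed direction with no call; 2 reversed, both without the 3 typical baseline arrays, where 1 typical baseline array remains. These were MYH10 in the typical minus slow change at week 3 (0.27, adjusted p = 1; reported -5.70) and AP2M1 in typical against slow at baseline (0.22, adjusted p = 0.947; reported -3.93). Of the gene list values and counts of called lists, 1752 kept, 69 lost the call, 20 gained one and 139 moved (a change of direction with no call, or a count that moved by over 1.5 times). Quantile normalization placed the median change of tested probe sets at 0.00 and -0.01, against -0.05 and -0.06 as reported. Values at the floor, 21.6% to 31.5% of an array, limit what dim genes can show. With an estimated correlation, 4 lists were called at week 3, 1 at week 7, 0 between the weeks and 0 for the rapid minus slow change at week 7, against 8, 7, 7 and 3.

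The counts that moved by over 1.5 times follow; fits with fewer arrays or fewer probe sets have less power by construction, and otherwise the cause was not tested. Without the replicate block, the counts were 353 for week 3 in all animals, 30 for week 3 in rapid animals, 15 for week 3 in slow animals and 22 for week 7 in slow animals. It also gave 1 for the rapid minus slow change at week 3. With all 36 arrays and a random replicate block, the counts were 1231 for groups at baseline, 9 for rapid against slow at baseline, 16 for groups at week 3 and 2 for rapid against slow at week 3. Further counts there were 3 for groups at week 7 and 3 for rapid against slow at week 7. Quantile normalization gave 131 for the change at week 7 among groups, 224 for groups at baseline, 5 for rapid against slow at baseline and 1 for groups at week 3. Others were 3 for rapid against slow at week 3 and 7 for rapid against slow at week 7. A floor of 100.2 units gave 25 for week 3 in rapid animals, 13 for week 3 in slow animals, 24 for week 7 in slow animals and 1 for the rapid minus slow change at week 3. It also gave 214 for groups at baseline, 1 for groups at week 3 and 1 for rapid against slow at week 3. A floor of 501 units gave 48 for week 3 in slow animals, 319 for the change at week 7 among groups, 2 for the rapid minus slow change at week 7 and 0 for rapid against slow at baseline. Further counts there were 5 for groups at week 3, 5 for rapid against slow at week 3, 4 for groups at week 7 and 3 for rapid against slow at week 7. A floor of 1002 units gave 758 for week 7 in all animals, 118 for week 7 in rapid animals, 65 for week 3 in slow animals and 78 for week 7 in slow animals. Others were 474 for the change at week 3 among groups, 0 for the rapid minus slow change at week 3, 427 for the change at week 7 among groups and 0 for the rapid minus slow change at week 7. Further counts there were 0 for rapid against slow at baseline, 14 for groups at week 3, 16 for rapid against slow at week 3 and 5 for groups at week 7. It also gave 2 for rapid against slow at week 7. No filter gave 7 for rapid against slow at week 7. The filter of 1002 units on 12 arrays gave 117 for the change at week 3 among groups, 0 for the rapid minus slow change at week 3, 95 for the change at week 7 among groups and 0 for the rapid minus slow change at week 7. It also gave 1 for rapid against slow at baseline, 0 for groups at week 3, 2 for rapid against slow at week 3 and 4 for groups at week 7. Others were 2 for rapid against slow at week 7. Trended and robust moderation gave 54 for week 3 in slow animals, 1 for the rapid minus slow change at week 3, 674 for groups at baseline and 1 for rapid against slow at baseline. It also gave 1 for rapid against slow at week 3 and 7 for rapid against slow at week 7. A linear trend over the groups gave 2 for the change at week 3 among groups, 1 for the change at week 7 among groups, 0 for groups at baseline and 0 for rapid against slow at baseline. Further counts there were 2 for rapid against slow at week 3, 0 for groups at week 7 and 0 for rapid against slow at week 7. Without the 3 typical baseline arrays that stood apart, the counts were 119 for week 3 in all animals, 168 for week 7 in all animals, 0 for week 7 against week 3 and 111 for week 7 in rapid animals. Others were 3 for week 3 in typical animals, 2 for week 7 in typical animals, 2 for the change at week 3 among groups and 2 for the change at week 7 among groups. Further counts there were 8 for groups at baseline and 5 for rapid against slow at baseline. With rapid and slow animals alone, the counts were 126 for week 3 in all animals, 177 for week 7 in all animals, 0 for week 7 against week 3 and 2 for the rapid minus slow change at week 7. Without the 2 rapid arrays of extreme spike controls, the counts were 0 for week 7 against week 3, 23 for week 3 in rapid animals, 38 for week 7 in rapid animals and 9 for groups at week 3. Further counts there were 1 for rapid against slow at week 3 and 3 for rapid against slow at week 7. Fits without 1 animal gave 296 to 944 for week 3 in all animals, 307 to 899 for week 7 in all animals, 0 to 2 for week 7 against week 3 and 2 to 60 for week 3 in rapid animals. The ranges were 15 to 76 for week 7 in rapid animals, 552 to 1729 for week 3 in typical animals, 491 to 1628 for week 7 in typical animals and 5 to 30 for week 3 in slow animals. They were 12 to 43 for week 7 in slow animals, 10 to 912 for the change at week 3 among groups, 1 to 5 for the rapid minus slow change at week 3 and 4 to 814 for the change at week 7 among groups. These fits gave 1 to 2 for the rapid minus slow change at week 7, 54 to 1444 for groups at baseline, 1 to 28 for rapid against slow at baseline and 0 to 9 for groups at week 3. Fits without 1 animal gave 0 to 5 for rapid against slow at week 3, 0 to 37 for groups at week 7, 0 to 24 for rapid against slow at week 7 and 0 to 5 for list scores.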

Other observations

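The look at the second principal component was chosen after the result was seen, as were the tests without the 3 typical baseline arrays. Of 25 cell cycle genes, 4 rose at week 3 (4 rose and 1 fell adjusted over the list alone), though the list was not called (adjusted p = 0.0887). They were BIRC5, an inhibitor of apoptosis active in mitosis (1.25 ± 0.37), the replication gene GINS1 (1.16 ± 0.32), the mitotic kinase gene PLK1 (1.16 ± 0.32) and the helicase subunit gene MCM6. Without the 3 typical baseline arrays that stood apart, GINS1 passed (adjusted p = 0.0354) and PLK1 and BIRC5 did not (adjusted p = 0.881 and 0.541); without the replicate block GINS1 and BIRC5 did not (0.0896 and 0.0658).

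Single genes of the monocyte, plasma cell and dendritic cell lists passed at week 7, while these lists were not called (adjusted p = 0.528, 0.435 and 0.528). MNDA, a nuclear antigen of myeloid cells, rose by 0.88 ± 0.22 at week 3 and 1.16 ± 0.22 at week 7, each in 10 of 12 animals, but not without the replicate block (adjusted p = 0.21 and 0.0839). VCAN, which encodes the proteoglycan versican, fell by 0.96 ± 0.26 at week 7 in 11 of 12 animals (adjusted p = 0.0254; 0.0577 without the replicate block). IGHM, the immunoglobulin M heavy chain gene, rose by 0.59 ± 0.17 at week 7 in 11 of 12 animals (adjusted p = 0.0353; 0.229 without the 3 arrays). CD1C, a lipid antigen presenting gene of dendritic cells, changed by 1.78 ± 0.54 at week 7 (adjusted p = 0.0445; 0.0741 without the replicate block).

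On the second principal component (9.26% of variance) the 12 arrays of slow animals lay above 0 at all 3 times, the highest at 41.0. The 12 arrays of rapid animals lay between -35.0 and 24.4, the highest being the baseline array of animal 3206. Typical animal 3137 lay at 31.6, 15.4 and 17.8, typical animal 3204 at -30.9, -31.8 and -22.7, typical animal 3142 at 0.214, -2.41 and -10.2 and typical animal 3226 at 22.2, -33.4 and -39.3, at baseline, week 3 and week 7. Array intensities differed along this component too. The highest array, slow 3220 at baseline, had the lowest median (622 units), and the lowest, typical 3226 at week 7, had 1066. The baseline arrays of 3137 and 3226 went the other way, with medians of 1255 and 1232. Whether progression or array quality sets this component was not tested.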
